A study of Mus musculus with 4 samples.

How the data were processed

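Gene expression was measured in mouse C2C12 cells, 48 hours after the medium was changed from 10% fetal bovine serum to 2% horse serum, both with 25 mM glucose. Per the labels' protocols, the cells were stable transfectants kept under 750 µg/mL hygromycin B during growth, and biotin-labelled RNA was made from 250 ng of total RNA for 3' expression arrays. There were 2 shControl and 2 shLSD1 arrays, grouped by their labels. Each value deposited by the authors is a signal intensity per probe set on a linear scale. Per the submitters' processing notes it comes from MAS5 and Affymetrix Expression Console, whose versions are not given in the sources used here. The mean of each array after trimming 2% of the probe sets at each end was 500.003, so the arrays had been scaled by 1 factor each. MAS5 signals near background are noisy on a log scale, and one factor per array leaves any difference in the shape of the distribution in place.

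Signals under 1 were set to 1 before taking log2, which affected 505 to 704 of 45101 probe sets per array. The annotation table used gave exactly 1 gene symbol for 34945 probe sets, several for 932 and none for 9160, with 64 control probe sets left out. Symbols were checked through the gene ID against a gene table of assembly GRCm38.p6, and 0 needed an update. That table served for names and for the order of neighbouring genes, and its coordinates were used only to set that order. Each of 18193 genes was represented by 1 probe set with a single symbol, with those of the type prone to cross-hybridisation avoided where another existed, and then by the brightest. The 10879 genes above the median mean log2 signal of all probe sets, 6.03 or a signal of 65.4, were tested, and 7314 lay below it. Cpt1b had no probe set with a single symbol.

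The groups were compared with limma 3.58.1 (lmFit and eBayes with an intensity trend, 7.54 total degrees of freedom) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are shLSD1 minus shControl. Gene lists, 26 in number, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists. Of 759 genes written in the lists, each counted once over all lists, 694 had a usable probe set and 578 were tested. The alternative list tests were camera with an estimated correlation, fry with statmod 1.5.0, and the percentile of each median among 10000 random lists matched on signal. Figures were drawn with matplotlib 3.10.9.

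The genes named are Kdm1a, the 12 largest rises and 12 largest falls past the threshold whose groups did not overlap (unnamed gene models passed over), up to 4 members of each list with the smallest adjusted p, and a fixed set of muscle and metabolism genes. The design, the lists, this rule and all alternatives except the one without a run of neighbouring genes were chosen before the data were examined. The alternatives were a replicate block, each array left out, quantile normalization, median centring, log2(signal + 32), no filter and a stricter filter at log2 7.93, no intensity trend, robust variance, the mean of a gene's probe sets, every probe set, and other thresholds.

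The method was tested on simulated data for 10879 genes with the spread of these arrays and 200 changed genes. It recovered 40 of 67 genes changed by 0.5 on the log2 scale (59.7%), 54 of 67 changed by 1 (80.6%) and 63 of 66 changed by 2 (95.5%). There were 3 false calls among 10679 unchanged genes, or 1.88% of the calls. A simulated list of 25 genes shifted by 0.5 had a camera adjusted p of 2.50e-40. With an estimated correlation its adjusted p was 0.244, so that test missed a real shift of this size at 2 arrays per group. The simulated genes were drawn independently, so this does not show how the preset correlation of 0.01 performs on correlated lists. In the real lists the estimated correlation was 0.50 for sarcomere, 0.45 for slow fibre and 0.25 for myogenic genes. It was 0.16 for oxidative phosphorylation, 0.02 for fast fibre and cell cycle genes and 0.01 for matrix genes.

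The signal ratio of the 3' to the 5' control probe sets was 0.765, 0.755, 0.783 and 0.774 for Gapdh, and 1.18, 1.18, 1.19 and 1.16 for Actb, in shControl replicates 1 and 2 and shLSD1 replicates 1 and 2. The labels do not say that the arrays come from separate cultures, so the p-values measure the spread between these arrays, which may be technical. As far as the labels say, each hairpin is represented by 1 stable selection, so selection and knockdown are confounded.

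Among the 146 named genes, 45 that passed the threshold had another probe set above the filter. All other probe sets had the same sign for 42 of these, and at least 1 had the opposite sign for 3, which were Kdm5a, Nusap1 and Gadd45b.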

Results

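The transcriptome of C2C12 cells, an immortalised line of mouse myoblasts that fuse into myotubes when serum is lowered, was measured on 4 Affymetrix 3' expression arrays. Cells carried a stably selected plasmid encoding either a non-targeting short hairpin RNA (shControl, 2 arrays) or one directed against LSD1 (shLSD1, 2 arrays), and RNA was collected 48 hours after differentiation was induced. LSD1, encoded by Kdm1a, removes methyl groups from histone H3 and acts in repressive complexes with CoREST. The comparison asks which transcripts differ when LSD1 is depleted during differentiation. Each array gave a MAS5 signal for 45101 probe sets, with a median between 67.3 and 69.7 and a highest signal between 44842 and 49493. The number of arrays limits the precision. The correlation of log2 signals over tested genes, which are not independent replicates, was 0.993 between the shControl arrays and 0.991 between the shLSD1 arrays, against 0.977 to 0.978 across the groups.

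Kdm1a fell in both knockdown arrays. Its signal was 4603 and 4588 in shControl replicates 1 and 2, and 922 and 1034 in shLSD1 replicates 1 and 2. The log2 fold change was -2.23 (SE 0.07, n = 2 and 2; limma, Benjamini-Hochberg adjusted p = 2.89e-05), which leaves 21.3% of the control level. A second Kdm1a probe set gave -2.50 (SE 0.11, limma adjusted p = 3.49e-05), or 17.7% of control. The related demethylase gene Kdm1b measured -0.21 (SE 0.10, limma adjusted p = 0.196), and Rcor1, which encodes CoREST, measured 0.19 (SE 0.07, limma adjusted p = 0.121). Of 20 tested genes for partners of LSD1 and other demethylases, 0 rose and 1 fell (0 and 0 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.358). The gene that fell was Kdm5a, at -0.28 (SE 0.07, limma adjusted p = 0.0380), whose other probe sets ranged from -0.21 to 0.03. Its call was lost without either shControl array, without shLSD1 replicate 2, with no filter on dim probe sets, without the intensity trend and with the mean of its probe sets. Jade2 measured -0.03 (SE 0.16, limma adjusted p = 0.923).

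**Figure D1:**
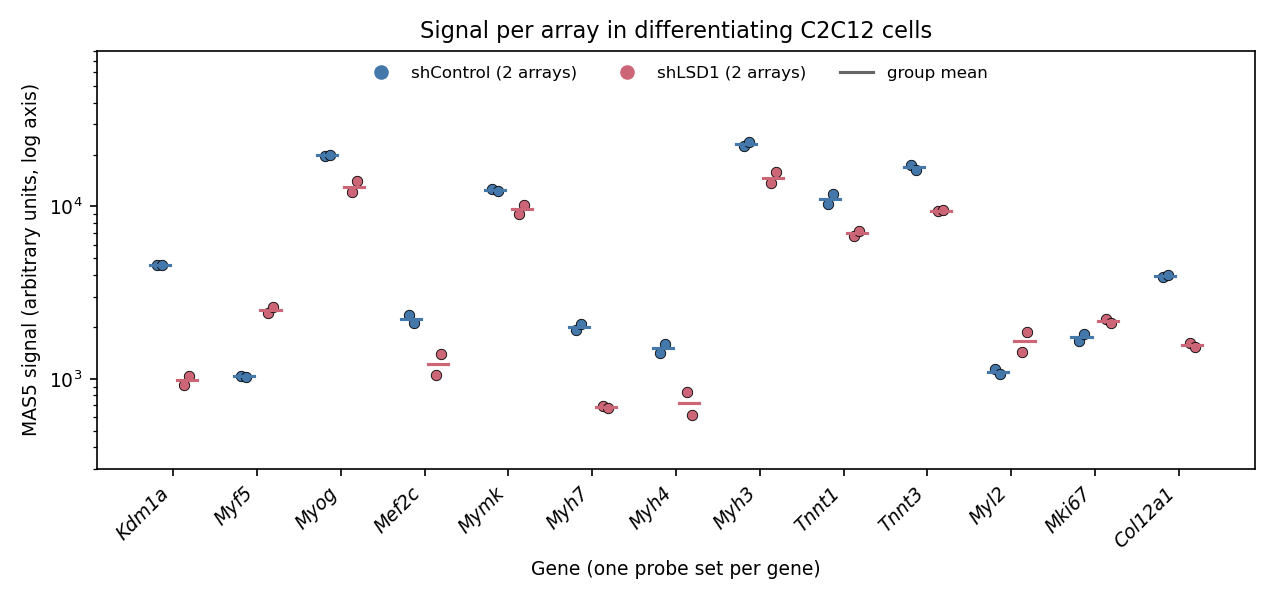
MAS5 signal on a log axis (arbitrary units) for 13 genes in the 4 arrays, with blue points for shControl, red points for shLSD1 and a line at each group mean. Kdm1a lies at 4603 and 4588 in shControl and at 922 and 1034 in shLSD1, and Myf5 and Myl2 are higher in shLSD1 while Myh7 and Tnnt3 are lower.

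Many genes of the contractile apparatus fell in the knockdown. Of 38 tested genes for the sarcomere and excitation-contraction coupling, 24 fell and 1 rose (27 and 1 adjusted over the list alone), with a median log2 fold change of -0.49 (camera adjusted p = 9.06e-15, and adjusted p = 0.379 with an estimated correlation). The perinatal myosin heavy chain gene Myh8 fell by 2.15 on the log2 scale (SE 0.15, limma adjusted p = 2.22e-04), Myl4 by 0.80, Lmod3 by 0.72 and Unc45b, a myosin chaperone gene, by 0.77. The embryonic myosin gene Myh3 fell by 0.64 (SE 0.07, limma adjusted p = 1.26e-03). Myosin heavy chain genes are close in sequence, so cross-hybridisation among them cannot be ruled out from the signals.

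Genes of slow and of fast fibres both moved mostly downward. In the slow list, 9 of 15 tested genes fell and 1 rose, with a median of -0.59 (camera adjusted p = 1.04e-06, and adjusted p = 0.379 with an estimated correlation). In the fast list, 10 of 19 fell and 1 rose, with a median of -0.49 (camera adjusted p = 3.22e-06, and adjusted p = 0.365 with an estimated correlation). Adjusted over the list alone, 9 slow genes fell and 1 rose, and 10 fast genes fell and 2 rose. The slow myosin gene Myh7 fell from a mean signal of 1998 ± 124 to 684 ± 11.4 (SD, n = 2 each), a log2 fold change of -1.55 (SE 0.08, limma adjusted p = 6.00e-05). Ankrd2 fell by 1.42, Casq2, the slow and cardiac calsequestrin gene, by 0.83, myoglobin (Mb) by 0.67, Tnnt1 by 0.67 and Tnni1 by 0.49. The slow member that rose was Myl2, at 0.58 (SE 0.12, limma adjusted p = 0.0174). Myl3 stayed below the signal filter. Among fast genes, Tnnt3 fell by 0.83, Tnni2 by 0.76, Casq1 by 1.18 and Myh4 by 1.06 (SE 0.14, limma adjusted p = 2.92e-03). Eya1, a transcriptional cofactor gene of the fast programme that is named here after its value was seen, rose by 1.17. Myh1 measured -0.17 (limma adjusted p = 0.253) and Myh2 -0.63 (limma adjusted p = 0.161). The calls of Myl2, Tnnc1 (-0.31) and Mylpf (-0.27) were lost without shControl replicate 1 and without shControl replicate 2. Without the intensity trend the calls of Myh4 (limma adjusted p = 0.0548), Myl2, Tnnc1 and Mylpf were lost, and that of Mb was lost with the mean of its probe sets.

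Myogenic transcription factors went in different directions. Myf5, a determination factor of myoblasts, rose from a mean signal of 1035 ± 6.70 to 2508 ± 149 (SD, n = 2 each), a log2 fold change of 1.28 (SE 0.07, limma adjusted p = 7.94e-05). Myogenin (Myog), which drives terminal differentiation, fell by 0.61 (SE 0.07, limma adjusted p = 1.46e-03), and Mef2c fell by 0.88 (SE 0.13, limma adjusted p = 3.92e-03). Myod1 measured -0.17 (SE 0.10, limma adjusted p = 0.319). The fusion genes Mymx and Mymk fell by 0.55 and 0.38. Of 20 tested genes for myogenic regulation and fusion, 8 fell and 2 rose, and adjusted over the list alone 9 fell and 3 rose. The list median was -0.15 (camera adjusted p = 4.76e-03, and adjusted p = 0.561 with an estimated correlation). Without the intensity trend the calls of Myog (limma adjusted p = 0.0511), Mef2c (limma adjusted p = 0.0638), Mymx (limma adjusted p = 0.0559) and Mymk were lost, and that of Mymk also without either shControl array. Of 24 genes for satellite and reserve cells, 5 rose and 4 fell (7 and 5 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.764). The Notch ligand gene Jag1 fell by 1.19 (a call lost with the mean of its probe sets), Hes6 fell by 0.69 and Met, the hepatocyte growth factor receptor gene, rose by 0.58. Pax7 measured -0.65 (SE 0.21, limma adjusted p = 0.0741).

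Genes of oxidative phosphorylation and mitochondrial biogenesis showed few changes. Of 74 tested genes for oxidative phosphorylation, 4 fell and 1 rose, the same counts adjusted over the list alone, and the median was -0.04 (camera adjusted p = 0.0415, and adjusted p = 0.750 with an estimated correlation). The members that fell include the muscle isoforms of cytochrome c oxidase Cox6a2 (-1.10, SE 0.08, limma adjusted p = 2.48e-04) and Cox8b (-0.63, a call lost without shControl replicate 2 and without the intensity trend), while the muscle isoform Cox7a1 rose 2.30-fold (SE 0.16 on the log2 scale, limma adjusted p = 2.58e-03). The call of the list was also lost without shControl replicate 1 (-0.049, camera adjusted p = 0.130), without shControl replicate 2 (-0.036, camera adjusted p = 0.0546) and without shLSD1 replicate 1 (-0.011, camera adjusted p = 0.397). Of 19 regulators of mitochondrial biogenesis, 0 changed over all genes tested or adjusted over the list alone, with a median of 0.01 (camera adjusted p = 0.787), and 0 had an unadjusted limma p under 0.05. Ppargc1a, the gene for the coactivator PGC-1alpha, measured -0.14 (SE 0.28, limma adjusted p = 0.783), Ppargc1b 0.16 (limma adjusted p = 0.323) and Esrra 0.19 (limma adjusted p = 0.236), and Esrrg stayed below the signal filter. In the list for the tricarboxylic acid cycle and pyruvate oxidation, 3 of 21 genes rose and 1 fell, also adjusted over the list alone, with a median of -0.07 (camera adjusted p = 0.343). Idh2 (0.28) and Idh3b (0.23) rose and Mpc1 (-0.19) fell, and these calls were lost without the intensity trend and with the mean of a gene's probe sets. Citrate synthase (Cs) rose by 0.17 (SE 0.05, limma adjusted p = 0.0448), a call lost without either shControl array, with median centring, with no filter on dim probe sets, without the intensity trend and with the mean of its probe sets.

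Fuel-handling genes moved both ways. Of 28 tested genes for fatty acid uptake and oxidation, 5 rose and 1 fell, also adjusted over the list alone. Their median of -0.01 and mean of 0.03 differ in sign (camera adjusted p = 0.764). Lipoprotein lipase (Lpl) rose by 0.68, the lipid droplet gene Plin2 by 0.72 and the fatty acid transporter gene Slc27a1 by 0.77 (a call lost without shControl replicate 2 and without the intensity trend), while the fatty acid translocase gene Cd36 fell by 1.17 (SE 0.12, limma adjusted p = 1.09e-03). Pdk4, a kinase gene that limits pyruvate oxidation, rose by 0.51 (SE 0.09, limma adjusted p = 0.0109), a call lost without either shControl array. Of 24 glycolysis genes, 4 rose and 5 fell, and adjusted over the list alone 8 rose and 5 fell, with a median of 0.06 (camera adjusted p = 0.380). The isoforms Pfkp and Hk1 rose by 0.76 and 0.50, and the muscle genes Pgam2 and Pygm fell by 0.77 and 0.69. Hk2 measured 0.03 (limma adjusted p = 0.854), Ldha 0.03 (limma adjusted p = 0.663) and Slc2a4 0.36 (SE 0.36, limma adjusted p = 0.547).

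Many proliferation genes rose and many matrix genes fell in the knockdown. Of 43 tested cell cycle genes, 26 rose and 0 fell (30 and 1 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 4.42e-11, and adjusted p = 0.365 with an estimated correlation). Ube2c, which acts in mitotic exit, rose by 0.90 (SE 0.06, limma adjusted p = 2.13e-04), cyclin D1 (Ccnd1) by 0.82 and Kif20a by 0.71. Nusap1 rose by 0.64, while its other probe set gave -0.27 and its call was lost with the mean of the probe sets. Mki67 rose by 0.32 (SE 0.07, limma adjusted p = 0.0206), a call lost without either shControl array and without the intensity trend. Of 33 extracellular matrix genes, 23 fell and 0 rose (26 and 0 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 2.26e-15, and adjusted p = 0.352 with an estimated correlation). The collagen gene Col12a1 fell by 1.33 (SE 0.06, limma adjusted p = 3.55e-05), tenascin C (Tnc) by 1.33, Col5a1 by 0.83 and Ccn2, the connective tissue growth factor gene, by 1.69. Of 20 genes for TGF-beta and BMP signalling, 6 fell and 1 rose, and adjusted over the list alone 10 fell and 2 rose. The median was -0.21 (camera adjusted p = 0.0288, and adjusted p = 0.376 with an estimated correlation), and the call was lost without shControl replicate 1 (-0.14) and without shLSD1 replicate 2 (-0.16). Smad6 fell by 1.15, Inhba by 0.52 and follistatin (Fst) by 0.48, and each of these calls was lost without shControl replicate 1, and that of Smad6 also without shControl replicate 2. Those of Inhba and Fst were also lost without the intensity trend, and that of Inhba with the mean of its probe sets.

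**Figure D2:**
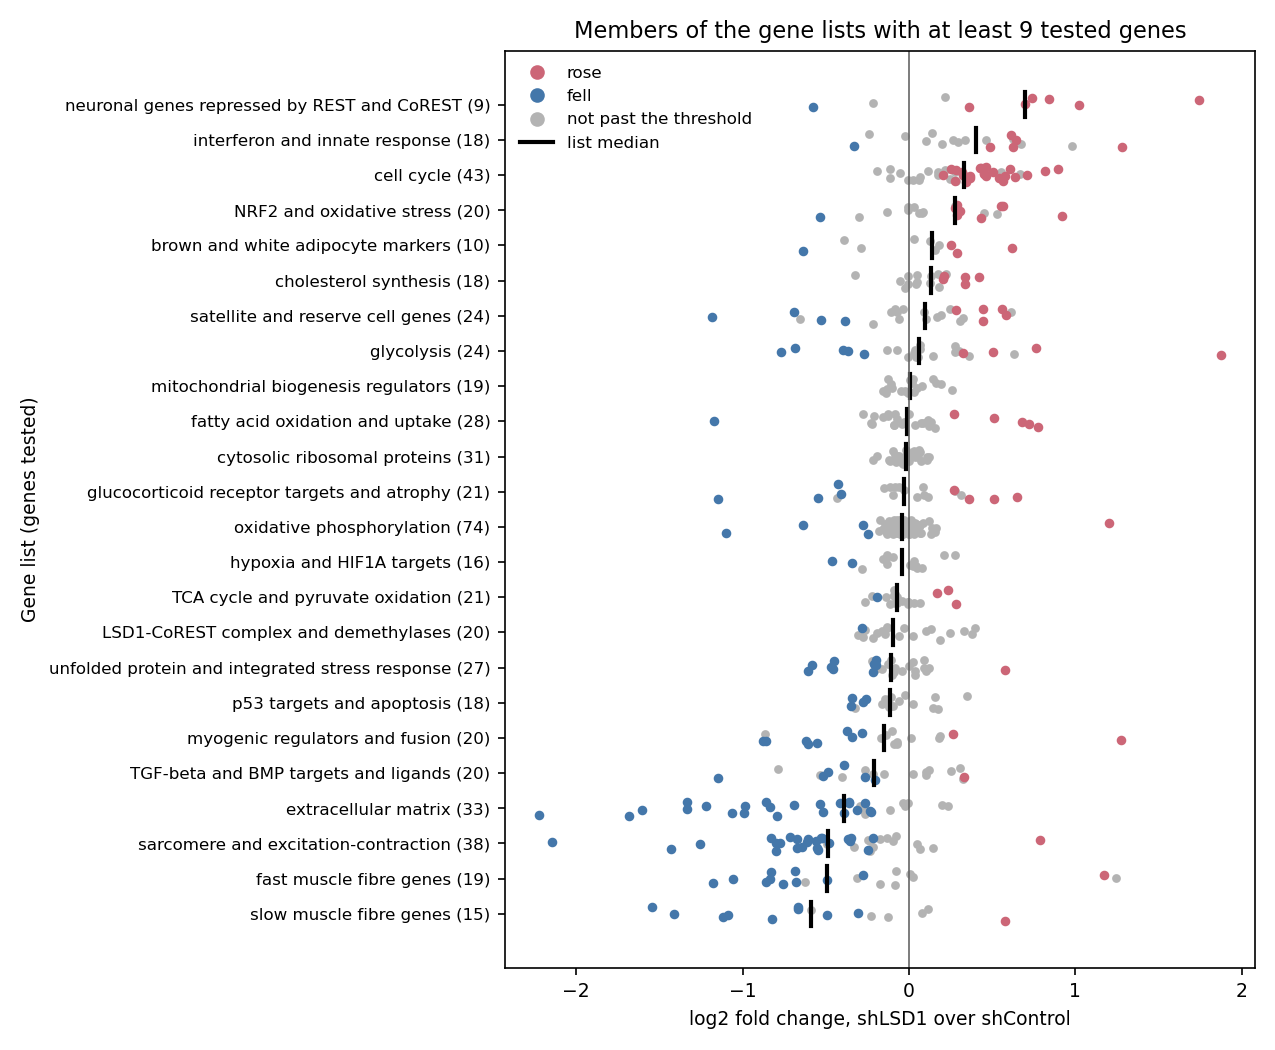
Log2 fold change (shLSD1 over shControl) of each tested member of the gene lists with at least 9 tested genes, with red for genes that rose, blue for genes that fell, grey for genes not past the threshold and a black bar at the list median. The medians run from -0.59 for slow fibre genes to 0.70 for neuronal genes, with oxidative phosphorylation at -0.04.

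Among the tested neuronal, interferon-related and antioxidant genes, more rose than fell, and many did not pass the test. The list of neuronal genes that REST and CoREST repress in other tissues also holds, as written, the repressor gene Rest itself. Only 9 of its 30 measured genes passed the signal filter. Of these, 6 rose and 1 fell (6 and 2 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 0.0166, and adjusted p = 0.376 with an estimated correlation). Gap43 rose by 1.74 (SE 0.21, limma adjusted p = 1.77e-03), Stmn2 by 1.02 and Nefl by 0.70, and Bdnf fell by 0.58. With no filter on dim probe sets the median of this list was -0.088, and its call was also lost with the stricter filter (0.53, camera adjusted p = 0.0927). Of 18 interferon and innate response genes, 5 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 2.35e-03, and adjusted p = 0.376 with an estimated correlation). The class I antigen gene H2-K1 rose by 1.28, with the limit that class I genes are close in sequence. The other H2-K1 probe sets above the filter gave 0.41 and 0.60, and with the mean of its probe sets H2-K1 measured 0.61 and its call was lost (limma adjusted p = 0.0597). B2m, which encodes their shared light chain, rose by 0.49. Of 20 NRF2 and oxidative stress genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 9.49e-03, and adjusted p = 0.376 with an estimated correlation). Nqo1 rose by 0.92 and Tkt by 0.57. Of 18 cholesterol synthesis genes, 5 rose and 0 fell (8 and 1 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.0188, and adjusted p = 0.376 with an estimated correlation). Insig1 rose by 0.42 and Fdft1 by 0.34. The calls of Nefl, Bdnf, Nqo1, Tkt, Insig1 and Fdft1 were lost without at least 1 of the shControl arrays. Those of Nefl, Bdnf, Tkt, Insig1 and Fdft1 were also lost without the intensity trend, and those of Tkt and Fdft1 with the mean of a gene's probe sets.

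In the list for the unfolded protein and integrated stress responses, more genes fell than rose. Of 27 tested, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 1.92e-03, and adjusted p = 0.376 with an estimated correlation). Asparagine synthetase (Asns) fell by 0.61, Mthfd2 by 0.58, Psat1 by 0.46 (a call lost without the intensity trend) and Herpud1 by 0.47. Herpud1 lies in a run of 50 neighbouring genes with a median of -0.32. Of 18 p53 target and apoptosis genes, 4 fell and 0 rose, also adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.0415, and adjusted p = 0.376 with an estimated correlation). That call was lost without shControl replicate 1 (-0.10), without shControl replicate 2 (-0.15) and without shLSD1 replicate 2 (-0.12). The cyclin-dependent kinase inhibitor gene Cdkn1a fell by 0.34, a call lost without either shControl array and without the intensity trend.

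The other lists tested with camera did not pass it, and the epithelial markers had no list test. In the list for glucocorticoid receptor targets and atrophy, 4 of 21 genes rose and 4 fell, and adjusted over the list alone 4 rose and 5 fell, with a median of -0.03 (camera adjusted p = 0.787). Dusp1 rose by 0.65 and Hsd11b1, which regenerates active glucocorticoid, fell by 1.15, a call lost without shControl replicate 2. Both calls were lost without the intensity trend. The receptor gene Nr3c1 measured -0.15 (limma adjusted p = 0.391). Of 16 hypoxia genes, 2 fell and 0 rose, also adjusted over the list alone, with a median of -0.05 (camera adjusted p = 0.343). Of 31 genes for cytosolic ribosomal proteins, 0 changed over all genes tested or adjusted over the list alone, with a median of -0.02 (camera adjusted p = 0.646), and 2 had an unadjusted limma p under 0.05. Markers of other cell types were mostly too dim to test. Of 10 tested adipocyte markers, 3 rose and 1 fell, also adjusted over the list alone (median 0.14, camera adjusted p = 0.584). Scd1 (0.29), Pnpla2 (0.62) and Fasn (0.25) rose, and Cox8b (-0.63), also counted above as a muscle isoform of cytochrome c oxidase, fell. Each of these calls was lost without the intensity trend. Of 24 measured epithelial markers, from a list written after some of them had been seen to rise, 18 stayed below the signal filter, and of the 6 tested 4 rose and 0 fell. Cdh1 and Ocln, which are among those 4, had control signals under the filter and were tested only because of their shLSD1 signals. Of 3 tested bone and cartilage markers, 0 changed, and adjusted over the list alone 1 rose (median 0.18, camera adjusted p = 0.621), the 1 with an unadjusted limma p under 0.05. Of 2 tested markers of blood, macrophages and endothelium, 0 changed over all genes tested or adjusted over the list alone (camera adjusted p = 0.787), and 0 had an unadjusted limma p under 0.05.

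Among single genes, 9 of the 12 named rises started from control signals under the filter of 65.4, so their size depends on the background. These 9 passed the filter, which uses the mean over the 4 arrays, only through their shLSD1 signals. Nnmt, nicotinamide N-methyltransferase, rose by 3.23 on the log2 scale (SE 0.47, limma adjusted p = 4.09e-03), from 42.5 and 18.0 in shControl to 355 and 189 in shLSD1, and by 2.26 with log2(signal + 32). The deubiquitinase gene Uchl1 rose by 3.09 (SE 0.13, limma adjusted p = 3.25e-05), from 109 and 118 to 918 and 1018, and by 2.78 with log2(signal + 32). The adhesion gene L1cam rose by 2.27 (SE 0.10, limma adjusted p = 3.55e-05), from 325 and 338 to 1492 and 1715. The other named rises were Mndal (2.71), Tpd52l1 (2.69), Tgm5 (2.43), Pof1b (2.38), the keratin gene Krt19 (2.36), Cd24a (2.34), Csf2rb (2.23), Rab39b (2.21) and Insl6 (2.14). Mndal belongs to a family of similar interferon-inducible genes. With log2(signal + 32) Tpd52l1 measured 1.74 and Tgm5 1.53. The calls of Tpd52l1, Tgm5 and Csf2rb were each lost without at least 1 array, and those of Nnmt, Tpd52l1, Tgm5, Csf2rb and Insl6 without the intensity trend. With the mean of a gene's probe sets Tpd52l1, Tgm5 and Csf2rb also lost theirs, as did Tpd52l1 and Tgm5 with no filter on dim probe sets. Among the falls, Cilp, a cartilage matrix gene, measured -3.85 (SE 0.13, limma adjusted p = 2.89e-05), from 1273 and 1270 to 96.4 and 80.6. The growth factor gene Igf1 fell by 2.82 (SE 0.14, limma adjusted p = 6.00e-05), from 730 and 851 to 118 and 105. Gprin3 (-2.37), the Wnt antagonist gene Sfrp2 (-2.33), Fmod (-2.22), the glutamate transporter gene Slc1a3 (-2.18), Ccn5 (-1.81), Aspn (-1.78), Camk1g (-1.77) and Mylk4 (-1.74) also fell. Gprin3, Sfrp2 and Fmod had mean shLSD1 signals of 50.9, 59.5 and 35.8, under the filter of 65.4, as did Slc1a3 in shLSD1 replicate 2 (49.1), so the size of these falls depends on the background. The call of Slc1a3 was lost without shControl replicate 1, without the intensity trend and with the mean of its probe sets.

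**Figure D3:**
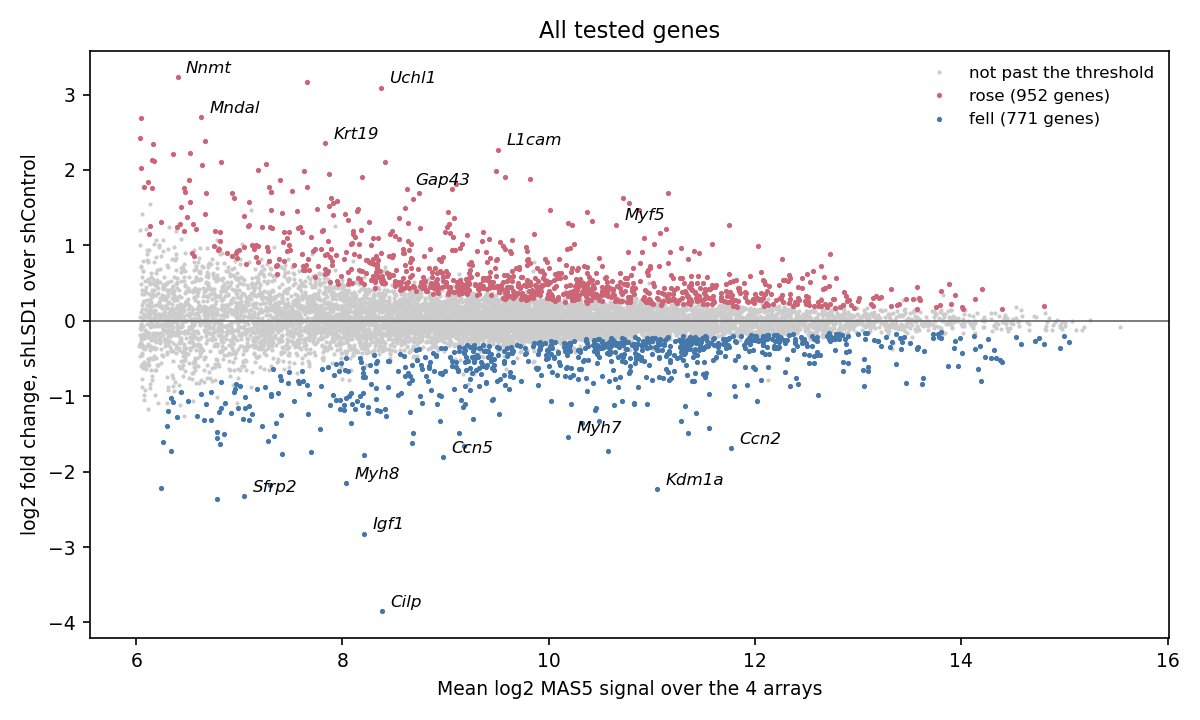
Log2 fold change (shLSD1 over shControl) against the mean log2 MAS5 signal over the 4 arrays for all tested genes, with red for the 952 that rose, blue for the 771 that fell and grey for the rest. Cilp lies at -3.85 and Uchl1 at 3.09, and dim genes at the left scatter more widely than bright ones.

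Over all 10879 genes tested, 1723 changed (15.8%), of which 952 rose and 771 fell (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 148 rose and 101 fell at least 2-fold. At an unadjusted p under 0.05 the count was 3369. The groups did not overlap for 6537 genes, or 60.1%, where chance gives 33.3% for 2 against 2 arrays. The count fell to 580 without shControl replicate 1 and to 582 without shControl replicate 2, and it was 637 without the intensity trend and 894 with the mean of a gene's probe sets. Quantile normalization gave 943 rising and 787 falling, and median centring, which shifts all genes of an array alike, gave 874 and 927. Of 26 lists, 14 passed the camera test with the preset correlation and 0 with an estimated one.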

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

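The only alternative added after seeing the data left out the run of neighbouring genes described among the other observations, and it gave 1687 changed genes. The main count of 1723 changed genes (952 rose, 771 fell) moved by over 1.5 times in these settings: no intensity trend, 637 (375 and 262); the mean of a gene's probe sets, 894 (491 and 403); an adjusted p under 0.10, 2596 (1437 and 1159); a 2-fold limit added, 249 (148 and 101); 2-fold with groups apart and no test, 272 (163 and 109). Leaving out 1 array gave 580 to 2192 changed, 349 to 1151 that rose and 228 to 1041 that fell, with the lone array assumed to vary like the other group. The low counts came without shControl replicate 1 (580) or 2 (582), and the fits without shLSD1 replicate 1 (1915) or 2 (2192) gave more. Scaling gave 1730 (943 and 787) with quantile normalization and 1801 (874 and 927) with median centring, which shifts all genes of an array alike. The deviations of same-numbered arrays correlated at 0.00287. That gave no sign of pairing over all tested genes, but it cannot exclude a shared effect on part of them. With the replicate block 2220 genes were called, 1718 of them shared with the main count. Kdm1a fell in all 14 settings run for it, the main one included, with log2 fold changes from -2.37 to -2.15. The other 145 named genes include some, such as Myod1 and Ldha, that had no call in the main fit to lose. Of 145 named genes, 52 lost their call without the trend, 37 without shControl replicate 1, 39 without shControl replicate 2 and 20 with the mean of probe sets, besides Pnpla2, which also lost its call there and turned to -0.83 (adjusted p = 0.537). The median of the oxidative phosphorylation list kept its sign but lost its call with the replicate block (-0.041, adjusted p = 0.0659), quantile normalization (-0.030, 0.288), the stricter filter (-0.041, 0.0568), no trend (-0.041, 0.103), the mean of probe sets (-0.026, 0.147), an estimated correlation (-0.041, 0.750), fry (-0.041, 0.286) and random lists (-0.041, 0.660), and it ranged from -0.059 to -0.011 with 1 array left out. The slow (-0.59), fast (-0.49) and myogenic (-0.15) lists lost their calls with an estimated correlation, as did all 14 lists that had passed, and the myogenic list also under fry (-0.15, adjusted p = 0.286). Of the 26 lists, 9 passed fry, where the sarcomere (adjusted p = 0.0527), TGF-beta (0.0527) and NRF2 (0.0661) lists also lost their calls. The TGF-beta list lost its call with no filter (0.205), the stricter filter (0.0927) and no trend (0.0642), the neuronal list with the stricter filter (0.0927) and the cholesterol list with no trend (0.0518). The p53 list lost its call with quantile normalization (0.0531), the stricter filter (0.0663), no trend (0.0951), the mean of probe sets (0.147) and random lists (0.0836). The median of the neuronal list turned to -0.088 (adjusted p = 0.652) with no filter, which adds dim genes. The causes of the other shifts were not tested. Signals close to background limit the precision for dim genes.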

Other observations

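The scan for runs of neighbouring genes, the tests of chance placement, lower copy number, RNA integrity, array scaling and the share of myotubes, the comparison with windows of 51 genes and the split of the epithelial markers by control signal were chosen only after the result was seen. So were the next groups, genes of the insulin-like growth factor axis and of small leucine-rich proteoglycans. Of 13 tested genes of the growth factor axis, 4 fell and 2 rose (limma, adjusted over all genes tested). Igf1 fell by 2.82 (SE 0.14), Igf2 by 1.06 (SE 0.14), Ins2 by 1.02 (SE 0.17) and Igfbp7 by 0.36 (SE 0.04), while Igfbp5 rose by 0.39 (SE 0.06) and Igfbp6 by 0.49 (SE 0.09). The receptor gene Igf1r measured -0.16 (limma adjusted p = 0.242). Of 9 tested proteoglycan genes, 7 fell and 0 rose. Fmod fell by 2.22, Aspn by 1.78, Lum by 1.60, Prelp by 0.92, Ogn by 0.60, Bgn by 0.52 and Dcn by 0.23. As these groups were picked for their values, their counts are descriptions and no test of a shift was run.

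Genes adjacent in the order of assembly GRCm38.p6 fell together in a run of 50 tested genes from Calr to Herpud1, with 24 falling, 2 rising and a median log2 fold change of -0.32. Its strongest 25-gene window had a median of -0.365, and 4 of 1000 random gene orders gave a window as far from 0. That argues against chance placement of falling genes. A lower copy number of the run in the knockdown line stays open. Of its genes, 86% lay below 0 and their 75th percentile was -0.16, which its prediction, written afterwards, asks for. Of 39 other probe sets of these genes, 89.7% lay below 0 (median -0.30). However, the run was delimited by its low medians, which favours such values. A wider run around it came from 51-gene windows (Zfp617 to Nol3, 159 genes, median -0.21). The strongest window of that wider run had a median of -0.329, and 0 of 1000 orders gave one as far from 0. Of the wider run's genes, 72.3% lay below 0, and their 75th percentile was 0.02, above 0. The fall of muscle and matrix genes that lie in the run was not decided by its test. The 45 genes outside every list had a median of -0.32, within the largest 25-gene window of the random orders (0.396). The whole run also lies within that window, so the bound set beforehand could not decide. The later comparison with 51-gene windows (largest 0.219) would put the 45 genes outside. Only 5 of the 50 genes are in a list, and the median was -0.318 without them against -0.316 with them. Leaving out 5 of 50 genes could hardly have moved the median, so this comparison, made afterwards, does not test the list members as the cause. It shows only that the low median also holds for the 45 genes outside the lists. Muscle or matrix genes outside the lists were not examined. Regional control of transcription by LSD1 was not tested, and no DNA measurement was used here.

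Muscle genes fell while cell cycle genes rose. A difference in RNA integrity is argued against, because the 3' to 5' ratios of Gapdh and Actb differed between the group means by at most 1.024-fold. Scaling of the arrays is argued against as well for the fall of the sarcomere genes. Their weaker median over quantile normalization and median centring was -0.48. Median centring moved the median of all tested genes only from 0.004 to -0.020, so that part could hardly have come out otherwise. The rise of cell cycle genes was not part of this test. A smaller share of myotubes with unchanged content may contribute, but as the whole cause it would make muscle genes fall alike, and the log2 fold changes of 53 such genes had an SD of 0.62, or 6.27 times their median SE, with the limits that the brightest muscle genes, with control signals of 10000 or more, were left out and that some of the 53 are also expressed in unfused cells. Slower differentiation and a difference between the 2 stable selections remain untested hypotheses.

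For genes of other tissues that rose from dim levels, epithelial cells in the knockdown cultures stay open: 0 of Krt8, Krt18 and Epcam rose, but Krt8 measured 0.53 (limma adjusted p = 0.259), and the other two were below the filter, at 22.1 and 23.0 for Krt18 and 3.16 and 6.66 for Epcam in shLSD1, too dim to exclude such cells. The other part of that prediction, a median over 1 for the tested markers, decides nothing: of 24 measured markers 18 stayed below the filter, and the median of 1.16 over the other 6 includes Cdh1 and Ocln, which passed it only through their shLSD1 signals, while the 4 with control signals over it had a median of 0.73. Krt19, Cdh1 and Ocln had been seen to rise when the marker list was written, and the count was put forward as the deciding number after both were seen. Noise of MAS5 signals near background also stays open, since 12 of the 12 named rises stayed past the threshold with log2(signal + 32), a setting that dropped none of the 1723 calls, while Nnmt, Tpd52l1, Tgm5, Csf2rb and Insl6 lost theirs without the intensity trend and Tpd52l1 and Tgm5 with no filter. Whether more genes were switched on than off is open: 32 of 148 genes that rose 2-fold (21.6%) and 15 of 101 that fell 2-fold (14.9%) had the dimmer group under the filter (two-sided Fisher's exact test over genes, p = 0.192), and loss of repression by LSD1, which may account for these rises, was not tested.

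The count of 1723 changed genes was set against the other splits of the 4 arrays into 2 and 2. Of the 3 splits, 1 gave as many genes, the real one, and the highest of the others gave 0. With 3 splits no share under 0.05 can be reached.

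A second run of neighbouring genes, from Abcf1 to Slc35b2, held 27 tested genes with a median of 0.26, of which 8 rose and 0 fell. Its strongest 25-gene window had a median of 0.333, and 9 of 1000 random orders gave a window as far from 0. With 51-gene windows a run of 51 genes from Nuak2 to Crb1 had a median of -0.19, and 22 of 1000 random orders gave a window as far from 0.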
